A study of Saccharomyces cerevisiae with 17 samples.

How the data were processed

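RNA of a W303 MATalpha yeast strain with an empty centromeric URA3 plasmid, the same plasmid with wild-type SCH9, or with SCH9(2D3E), was compared on 17 Agilent arrays. Cultures grew at 30 C in synthetic medium without uracil. Per the labels' protocols, total RNA was prepared with RNeasy, amplified with a low-input linear kit and labelled with Cy3 (sampled just before rapamycin) or Cy5 (sampled 20 to 180 min after it). The sample names give 100 nM rapamycin, while the growth protocol writes the dose in a unit per volume that does not parse. A DMSO vehicle is named in the protocol, and vehicle cultures were not analysed here.

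The scanner's mean signals and local background medians are intensities per spot in each channel, deposited as written by Agilent Feature Extraction A.7.5.1, per the file headers. The deposited processed signals were background-corrected, spatially detrended and dye-normalized (LOWESS with a factor of 0.25, and a linear step) within each array, per the file headers. The deposited LogRatio column is log10 of processed Cy5 over processed Cy3. The authors' series matrix holds log2 values of the same arrays. Set against the scanner values, each of its columns equalled LogRatio times log2 of 10, so scale and direction are known, with column medians of 0 to 0.044 and no further centring. No file names the genome build of the array design, so no coordinates are given.

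Signals were read from 10789 spots, of which 526 were control spots, and corrected with limma's normexp (offset 50). Control spots were then left out, at weight 0 in the loess within each array (span 0.3), and spots with an outlier mark in either channel were set to missing (0 to 36 per array). Saturated spots were kept (2 to 16 probes per array in Cy5, 0 to 1 in Cy3). Spots of a probe were averaged, which gave 6256 probes, 4007 of them with 2 spots. A gene was tested if it was well above background in at least 1 channel on at least 9 arrays and had a value on at least 12 arrays and at 3 times per plasmid. This left 5985 genes and dropped 271. Genes carry the array's names. The systematic name was found for 5756 of 6256 probes in the reference gene table of assembly R64, which served for names only, and 500 kept the name in the file. Probes of near-identical paralogs, such as ribosomal protein gene pairs or CUP1-1 and CUP1-2, can cross-hybridise, so such genes are not separate measurements. Levels per channel were computed from the loess values with Aquantile scaling. Both steps use the average of the 2 channels, so each channel still enters the other's level through the scaling.

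Arrays were compared with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8). The fit used all 17 arrays with plasmid and time as factors and no interaction (9 residual degrees of freedom), eBayes moderation and Benjamini-Hochberg adjustment at 0.05. Contrasts were the response of each plasmid and of both controls against 0, the differences between plasmids, late minus early (120 and 180 min minus 20 and 30 min) and, from a fit with a slope per plasmid on log2 time, the slope of SCH9(2D3E) minus that of the controls. No replicate cultures are recorded, so the error is the spread of plasmid by time values, and culture, reference RNA and array effects shared by several arrays are not part of it. A response against 0 also leaves out the spread of the reference and holds any dye bias, since all arrays have 1 orientation.

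The 27 gene lists were cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerase I and III, translation factors, tRNA synthetases, mitochondrial ribosomal proteins, nitrogen catabolite repression, retrograde response, Msn2/Msn4 stress, Gcn4 amino acid synthesis, methionine and sulfate assimilation, purine synthesis, glycolysis, oxidative phosphorylation, autophagy, proteasome, phosphate regulon, iron regulon, histones, G1/S, G2/M, daughter-specific and M/G1, alpha-cell, a-cell, early meiotic, mitochondrially encoded and plasmid-borne genes. Each was tested with camera (preset correlation 0.01, and an estimated one as an alternative), adjusted over the lists of a contrast. Counts of members are given over all genes and, where different, adjusted over the list alone. List medians were also tested by exact two-sided permutation of the plasmid labels among the arrays of each time, on the 15 arrays of the 5 shared times for SCH9(2D3E) minus controls, with 64 arrangements for SCH9(WT) minus empty plasmid and 32 for SCH9(2D3E) minus SCH9(WT). The permutation treats arrays as independent, which a design without recorded replicate cultures does not grant.

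Genes are named by rule. For the control response these were the 10 highest and 10 lowest ratios past the threshold with 1 sign on all 12 control arrays, and for SCH9(2D3E) minus controls the 10 highest and 10 lowest differences with 1 sign at all 5 shared times. For each other contrast they were the 5 highest and 5 lowest past the threshold. Up to 4 members of each list with the largest absolute value past the threshold of the contrast in question, or the largest if none passed, were added, with SCH9 and URA3 always. Unnamed probes and Ty elements were not named. They numbered 1 among the lower genes of SCH9(2D3E) minus controls and 1 among those of SCH9(2D3E) minus SCH9(WT). The text gives a part of the genes so chosen.

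The design, the lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were no background correction, median centring in place of loess, loess with both ribosome lists at weight 0, the scanner software's log ratios, the authors' series matrix, no filter or a stricter filter on dim probes, only the shared times, no time term, trend and robust eBayes, array weights, slide as a random block (9 slides, each with 1 plasmid and at most 2 arrays), only the plasmids compared, the test channel alone for the differences between plasmids, quantile scaling of Cy3 levels, list means in place of medians, and each array left out in turn. Chosen after the data were seen were the values within each day on which images were read, plasmid and day as a random block, 1 value per plasmid and day, the test channel alone for late minus early and the slope, and late minus early or the slope within day 2 only.

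The design had assumed that each plasmid has 1 reference RNA, which would cancel in differences over time. This turned out not to hold. The Cy3 levels of arrays of the same plasmid correlated across genes at a median r of 0.999 within a day (18 pairs) and 0.925 between days (22 pairs), while those of different plasmids on the same day correlated at 0.993 (52 pairs). Genes are not independent replicates, so these values only describe the arrays. The day is that of image reading, and what else separated the 2 sets of arrays was not recorded.

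The fit, the list tests and the permutation were tested on simulated data with known answers (5971 genes). For SCH9(2D3E) minus controls the fit recovered 88 percent of genes seeded with 0.5 log2 and 100 percent of those seeded with 1 log2, with 7.4 percent false calls among all calls. For SCH9(WT) minus empty plasmid it recovered 87 and 100 percent, with 7.4 percent false, and for the slope difference 91 and 100 percent, with 2.1 percent false. Where a share of 0.5 of the error variance was common to the arrays of a plasmid and day, a fit with no real difference called 71 genes for SCH9(2D3E) minus controls, 100 against SCH9(WT), 93 against the empty plasmid and 191 for SCH9(WT) minus empty plasmid. The simulated error was scaled to the residual of the additive fit, which leaves out what all arrays of a plasmid share, and was independent between genes. These counts may thus be too low for the real arrays. The permutation of list medians passed 4.5 percent of 200 unchanged lists of 30 genes and 100 percent of lists shifted by 0.3 log2. Camera called 1 of 1 shifted list and 0 of 20 unchanged ones. Both list simulations used random genes, with errors drawn independently for each gene and array. They do not measure false calls where the genes of a list, or the arrays of a plasmid and day, move together.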

Results

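Transcript levels were measured on 17 dual-channel Agilent arrays of a W303 MATalpha yeast strain that carried 1 of 3 centromeric URA3 plasmids. The plasmid was empty (6 arrays), held wild-type SCH9 (6 arrays) or held SCH9(2D3E) (5 arrays), an allele with acidic residues in place of the sites that the kinase TORC1 phosphorylates. Sch9 is a kinase downstream of TORC1, and rapamycin inhibits TORC1. On every array the Cy5 channel held RNA taken 20, 30, 60, 90, 120 or 180 min after 100 nM rapamycin, and the Cy3 channel held RNA of the same plasmid's culture from just before the drug. An SCH9(2D3E) array at 60 min and vehicle cultures were not analysed here. No label named a deletion of the chromosomal SCH9 gene.

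Each combination of plasmid and time was a single array, with no replicate culture recorded, so the errors below come from the spread of plasmids and times around an additive fit, and the number of arrays limits their precision. The array images were read with Feature Extraction on 2 days, per the file headers, 6 arrays on day 1 (20 and 30 min) and 11 on day 2 (60 to 180 min, 3 of them of SCH9(2D3E)). The days of culture and of RNA preparation were not recorded. Median signal per array was 112 to 327 in Cy3 and 236 to 572 in Cy5, and 90.9 to 96.1 percent of probes in Cy3 and 94.7 to 97.6 percent in Cy5 lay well above background. The lowest Cy3 signals were those of SCH9(2D3E) on day 2, with medians of 112.3 to 116.5 and 90.9 to 91.6 percent of probes. The control arrays of that day had 144.8 to 270.3 and 92.7 to 96.1 percent. Differences of SCH9(2D3E) from the controls on day 2 thus coincide with a dimmer reference channel. The fit covered 5985 genes. All arrays had the same dye orientation, so a dye bias stays in every response measured against 0 and drops out of differences between plasmids.

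SCH9 and URA3 served as a check of the plasmid labels. Before rapamycin, the mean log2 Cy3 level of SCH9 was 7.86 (SD 0.03, n = 6) with the empty plasmid, 8.77 (SD 0.08, n = 6) with SCH9(WT) and 8.79 (SD 0.15, n = 5) with SCH9(2D3E), so both SCH9 plasmids carried a higher level, by 0.91 and 0.94 log2. Here n counts arrays and not cultures, and the SD does not measure the spread of replicate cultures. The URA3 marker had a lower Cy3 level with SCH9(WT) (−0.91 log2) and with SCH9(2D3E) (−1.05 log2) than with the empty plasmid. The probes do not separate the plasmid copy of SCH9 from the chromosomal one, nor the wild-type allele from SCH9(2D3E). After rapamycin SCH9 rose by 0.68 ± 0.03 log2 (SE, n = 12) in the control cultures and URA3 changed by −0.89 ± 0.03 log2 (limma adjusted p = 6.60e-11 and 7.15e-11).

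The first comparison asked which transcripts rapamycin changed where Sch9 stayed under the control of TORC1, in the empty and SCH9(WT) cultures together (n = 12). PDC6, a minor pyruvate decarboxylase, rose by 3.85 ± 0.09 log2 (SE), MLS1, the malate synthase of the glyoxylate cycle, by 3.74 ± 0.06, and GRE1, a stress-induced hydrophilin, by 3.66 ± 0.07. HSP30, a stress protein of the plasma membrane, rose by 3.40 ± 0.12 log2, CHA1, the catabolic serine and threonine deaminase, by 3.25 ± 0.07, and HXT5, a hexose transporter of slow-growing cells, by 2.67 ± 0.07. These are means over all times. On control arrays HSP30 was at 7.03 to 7.15 in Cy3 and 7.17 to 7.31 in Cy5 on day 1. On day 2 it was at 9.30 to 10.29 and 14.38 to 15.11, so its rise lay almost wholly in the day 2 arrays. GRE1 had control Cy5 levels of 7.10 to 7.73 on day 1 and 13.31 to 14.86 on day 2. The deepest decreases were almost all in cytosolic ribosomal protein genes. The change was −3.40 ± 0.10 log2 for RPS3, −3.35 ± 0.08 for RPL22A, −3.19 ± 0.08 for RPL5 and −3.16 ± 0.06 for RPS9B, and −3.04 ± 0.07 for ADH4, a zinc-regulated alcohol dehydrogenase gene (limma adjusted p at most 3.96e-11 for each gene named here).

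In all, 5286 of 5985 genes (88.3 percent) passed an adjusted p of 0.05 in limma, 2665 higher and 2621 lower, and 205 rose and 405 fell at least 2-fold. The median absolute change was 0.26 log2. Of the genes that passed, 2684 had the same sign on all 12 control arrays. The count holds many small shifts. Loess centres each array, so a change shared by most transcripts would not be seen, and the near balance of directions partly follows from it. Neither the dye bias nor the spread of the reference RNA is part of the error, and how much either adds to the count was not tested. The p measures only the spread of plasmid by time values around the additive fit. Changes over time that the plasmids share are taken out of it, and without a time term the count was 4531. Taken alone, the empty plasmid gave 4944 genes (2459 higher, 2485 lower) and SCH9(WT) 5039 (2578 higher, 2461 lower). Across genes, which are not independent replicates, the log2 ratios of empty and SCH9(WT) arrays of the same time correlated at r = 0.95 to 0.98 (6 pairs).

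Genes for making proteins fell in the controls. All 137 cytosolic ribosomal protein genes were lower (median −2.42 log2), as were 127 of 138 ribosome biogenesis genes (median −0.86), with 1 higher. Lower levels were also found for 40 of 41 translation factor genes (median −0.98), such as the elongation factor gene YEF3 (−2.43 ± 0.09 log2), and for all 19 tRNA synthetase genes (median −1.24), such as FRS1 for phenylalanine (−1.78 ± 0.04). Of 39 genes of RNA polymerases I and III, 30 were lower and 6 higher (median −0.39), and of 69 mitochondrial ribosomal protein genes 68 were lower and 1 higher (median −0.55). Camera, limma's test of a list against all other genes with a preset correlation of 0.01, called these 6 lists (adjusted p = 1.52e-26, 1.07e-12, 1.72e-10, 3.14e-07, 0.00244 and 1.21e-13 in the order given). With an estimated correlation the adjusted p was 0.447 for the cytosolic ribosomal protein, translation factor, tRNA synthetase and mitochondrial ribosomal protein lists and 0.714 for ribosome biogenesis and the polymerases.

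The ribosome biogenesis median was −2.12 log2 over the day 1 arrays, with all 138 genes lower, and −0.30 over the day 2 arrays, with 103 lower and 24 higher. Averaged over both controls, it went from −2.08 at 20 and 30 min through −0.60 at 60 min to −0.05 at 180 min. The cytosolic ribosomal protein list moved more slowly, from −0.97 at 20 min to −3.22 at 60 min and −2.33 at 180 min. Before the drug, in Cy3, ribosome biogenesis was lower on day 2 than on day 1 (−1.18 log2 with the empty plasmid, −0.62 with SCH9(WT) and −0.40 with SCH9(2D3E)). The later ratios thus have a lower denominator, and how much of the return belongs to time cannot be told apart from the day. NOP56, a core protein of methylating snoRNPs, changed by −2.59 ± 0.08 log2 over all times and MAK16, a factor of the large subunit, by −1.98 ± 0.07 (SE, n = 12).

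Catabolic and stress lists rose in the controls. Of 38 genes under nitrogen catabolite repression, 27 were higher and 9 lower (median 0.64 log2), among them the proline oxidase gene PUT1 (2.46 ± 0.06) and the allantoate permease gene DAL5 (2.32 ± 0.10). In the Msn2/Msn4 stress list 39 of 50 genes were higher and 7 lower (median 0.67), with the small heat-shock protein gene HSP26 at 2.30 ± 0.11 and the glycogen synthase gene GSY1 against the trend at −2.23 ± 0.07. The Cy5 probe of HSP26 was saturated on 7 of all 17 arrays, so its fitted value may be too low. Autophagy genes followed, 24 of 28 higher and 4 lower (median 0.58), including ATG9 (1.18 ± 0.03) and ATG8 (1.17 ± 0.04), which encode proteins of the growing autophagosome. Proteasome genes rose less, 25 of 33 higher and 1 lower (median 0.17), and so did daughter-specific and M/G1 genes, 12 of 17 higher and 1 lower (median 0.32). Of 26 genes of methionine synthesis and sulfate assimilation 19 were higher and 5 lower (median 0.45), with the sulfate permease gene SUL2 at 1.46 ± 0.10 (SE). The controls differed in this list, with a median of 0.18 log2 for the empty plasmid (0.07 within day 2, 11 higher and 8 lower) and 0.78 for SCH9(WT) (0.79 within day 2, 22 higher and 3 lower). Camera with the preset correlation called these lists (adjusted p = 0.00343, 6.70e-05, 3.91e-05, 0.000287, 0.0109 and 0.0228 in the order given). The adjusted p with an estimated correlation was 0.735, 0.714, 0.447, 0.476, 0.672 and 0.791.

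Glycolysis and the Gcn4 list were lower over all times, and more so on day 2. All 17 glycolytic genes were lower (median −0.92 log2), with the enolase gene ENO2 at −1.57 ± 0.07 and the hexokinase gene HXK2 at −1.37 ± 0.04. Within day 1 glycolysis had 2 higher and 10 lower (median −0.27), within day 2 all 17 were lower (−1.05), and in Cy3 the list was higher on day 2 than on day 1 by 0.80, 0.60 and 0.65 log2 for the empty, SCH9(WT) and SCH9(2D3E) plasmids. The Gcn4 list had 30 of 46 genes lower and 11 higher (median −0.47), LYS12 and LYS4 of lysine synthesis standing at −2.21 ± 0.05 and −2.02 ± 0.05 log2, but its day 1 median was 0.02, with 21 genes each way, against −0.65 on day 2. Camera called both (adjusted p = 2.28e-05 and 0.00265), and with an estimated correlation the adjusted p was 0.447 and 0.714.

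The other 13 lists were not called in the controls (camera, limma, adjusted p at least 0.0515). Respiratory chain genes split into 20 higher and 11 lower of 38 (19 and 11 when adjusted over the list alone; median 0.05), retrograde response genes into 4 and 2 of 10 (0.08), iron regulon genes into 12 and 2 of 21 (0.08), G1/S genes into 12 and 18 of 33 (−0.15) and alpha-cell genes into 1 and 3 of 4 (−0.43). The median of the rest changed sign with the scaling. Purine synthesis had 8 higher and 10 lower of 20 genes and a median of −0.11 log2, which median centring turned to 0.21. Early meiotic genes (10 higher and 2 lower of 16) went from 0.17 to −0.17, histones (2 and 5 of 8) from −0.27 to 0.13, and a-cell genes (4 and 1 of 7, or 3 and 1 over the list alone) from 0.03 to −0.49. The phosphate regulon (7 and 8 of 18) went from −0.04 to 0.04, mitochondrially encoded genes (2 and 4 of 7) from −0.10 to 0.05, G2/M genes (7 and 9 of 19) from 0 to 0.05, and the pair of plasmid-borne genes (1 and 1) from −0.10 to 0.19.

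**Figure D1:**
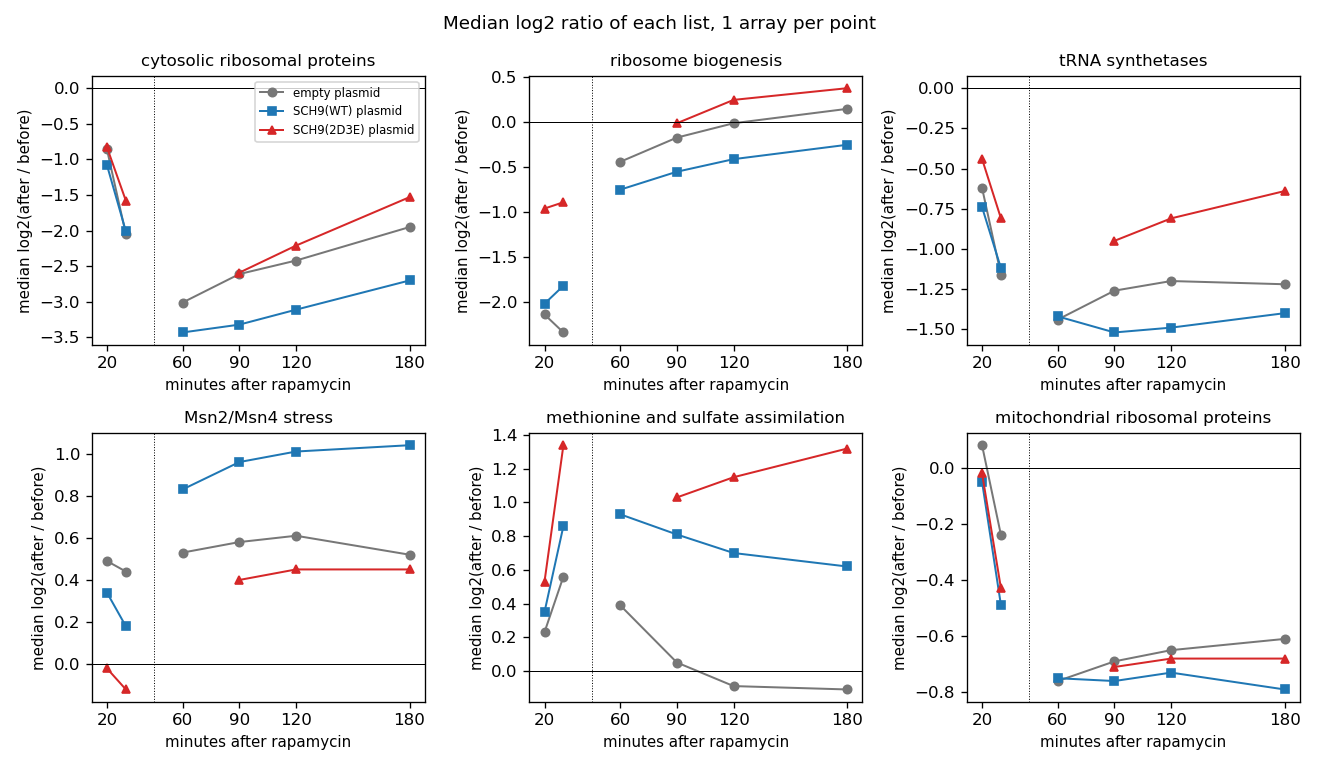
Median log2 ratio of each gene list (after over before rapamycin, 1 array per point) against minutes after rapamycin for the empty, SCH9(WT) and SCH9(2D3E) plasmids. The dotted line separates the arrays read on day 1 (20 and 30 min) from those read on day 2 (60 to 180 min).

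The central comparison asked which parts of the response to rapamycin were altered where Sch9 no longer needed TORC1, as SCH9(2D3E) minus the mean of both controls (n = 5 and 12). Genes of ribosome assembly had higher ratios with SCH9(2D3E). NSR1, a nucleolar protein of pre-rRNA processing, had a log2 ratio higher by 1.47 ± 0.23 (SE), DIP2, of the small-subunit processome, by 1.31 ± 0.17, MAK16 by 1.25 ± 0.13, NIP7, of large-subunit assembly, by 1.23 ± 0.17, and the nucleolar GTPase gene NOG1 by 1.22 ± 0.16. The adenylylsulfate kinase gene MET14 was higher by 1.37 ± 0.15 log2, and MET3, the ATP sulfurylase of the step before, by 1.17 ± 0.23. The ratio of each of these 7 genes was higher at all 5 shared times (limma adjusted p at most 0.00194). For genes picked by the naming rule from this difference, the sign and the threshold were required. On day 1 the ratio difference of NSR1 did not come from Cy5, where its level was 7.20 at 20 min and 7.28 at 30 min with SCH9(2D3E), against 7.64 and 7.30 with the empty plasmid and 7.24 and 7.27 with SCH9(WT). Control Cy5 levels on day 1 were 5.69 to 5.88 for DIP2 and 5.82 to 6.03 for NOG1. Those lie near the Cy3 level of the a-cell gene MFA2 on the same arrays (5.79 to 5.93), so the size of their day 1 differences is uncertain.

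Other genes had lower ratios with SCH9(2D3E). The difference was −1.04 ± 0.17 log2 (SE) for SPG1, needed in stationary phase, −1.01 ± 0.14 for HXT5, −0.97 ± 0.18 for ALD3, a stress-induced aldehyde dehydrogenase, and −0.87 ± 0.17 for SPG4, another stationary-phase gene. With SCH9(2D3E) the ratio of ALD3 ran from 0.01 log2 at 20 min to −1.03 at 180 min. The genes for the cytosolic catalase CTT1 and the transaldolase NQM1 differed by −0.82 ± 0.23 and −0.81 ± 0.08 log2. All 6 were lower at each of the 5 shared times (limma adjusted p at most 0.0129), as the naming rule required. PDC6, the gene with the largest rise in the controls, did not pass (difference 0.01 ± 0.16, limma adjusted p = 0.97).

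A total of 2939 genes (49.1 percent) passed in limma, 1585 higher and 1354 lower, of which 39 were higher and 2 lower by at least 2-fold. The balance of directions turned with the scaling, to 1387 higher and 1703 lower with the scanner software's log ratios and to 1337 higher and 1467 lower with median centring. The differences were small in most genes, and 2572 of the genes that passed had the same sign at all 5 shared times. Within day 1 the count was 2646 (1486 higher, 1160 lower) and within day 2 it was 3317 (1684 higher, 1633 lower). Both days called 1812 genes, 1650 of them with the same sign where independent lists would share 735. With each plasmid and day as a random block (estimated correlation 0.57) the count was 1406 (879 higher, 527 lower). With 1 value per plasmid and day (6 values) limma called 0 genes, with 1427 at an unadjusted p under 0.05 and a lowest adjusted p of 0.178.

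The ribosome biogenesis list had 131 of 138 genes higher and 0 lower (133 when adjusted over the list alone; median 0.67 log2). It held in day 1 (138 higher, median 1.05) and day 2 (124 higher, median 0.45). The median of the list was higher by 0.71 ± 0.41 log2 (SD over 5 times), with an exact two-sided permutation p of 0.00412, the smallest that moving the label within times allows, and an adjusted p of 0.0139. In the SCH9(2D3E) cultures alone the list had 54 genes lower and 10 higher than before rapamycin over all times (median −0.15), against 127 and 1 in the controls. That median averages 2 unlike sets of arrays. At 20 and 30 min the control median was −2.08 log2. The day 1 difference of 1.05 was smaller, so a fall remained there with SCH9(2D3E). On day 2 the control median ran from −0.60 at 60 min to −0.05 at 180 min, against a difference of 0.45. In the test channel, where the reference RNA enters only through the scaling, the median difference of the list was 0.46 log2.

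Polymerase, translation factor and tRNA synthetase genes were higher as well. Of 39 genes of RNA polymerases I and III, 26 were higher and 2 lower (median 0.38 log2), with RPA34 and RPA135 of polymerase I higher by 1.16 ± 0.15 and 0.63 ± 0.12 (SE). Translation factor genes had 36 of 41 higher and 1 lower (median 0.41), with YEF3 higher by 1.06 ± 0.17 log2, and tRNA synthetase genes 18 of 19 higher (all 19 over the list alone; median 0.45), with FRS1 higher by 0.68 ± 0.07. All 3 lists reached an exact permutation p of 0.00412, with mean shifts of 0.28 ± 0.13, 0.36 ± 0.12 and 0.44 ± 0.17 log2 (SD over 5 times). Of the cytosolic ribosomal protein genes 120 of 137 were higher and 0 lower (129 over the list alone; median 0.48), but the list median did not pass (0.46 ± 0.24 log2, exact permutation p = 0.0288, adjusted p = 0.0519). It passed in 10 of 27 settings, among them median centring (0.52 log2, permutation adjusted p = 0.0347) and the scanner software's log ratios (0.54, permutation adjusted p = 0.0427). The count of 120 was 62 within day 1, 120 within day 2 and 41 with plasmid and day as a block. The 69 mitochondrial ribosomal protein genes had a median difference of −0.01 log2 with 6 higher and 5 lower (3 and 4 over the list alone; mean shift −0.01, exact permutation adjusted p = 0.894).

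The stress and autophagy lists had lower ratios with SCH9(2D3E) than in the controls. The Msn2/Msn4, autophagy and proteasome lists each passed the permutation in 22 of 27 settings. In the Msn2/Msn4 list 38 of 50 genes were lower and 0 higher (39 lower over the list alone; median −0.37 log2), on day 1 (39 lower) and day 2 (44 lower). Its list median differed by −0.39 ± 0.05 log2 (SD over 5 times), with an exact permutation p of 0.0123 and an adjusted p of 0.0256. Of 28 autophagy genes 18 were lower and 0 higher (median −0.19), including the kinase gene ATG1 (−0.39 ± 0.07, SE) and the scaffold gene ATG31 (−0.43 ± 0.05), with a list shift of −0.18 ± 0.04 and 10 genes lower under the block. Proteasome genes were 12 lower of 33 (7 over the list alone; median −0.07; shift −0.06 ± 0.02) and 2 lower under the block. The exact permutation adjusted p was 0.0202 for autophagy and for the proteasome, and 0.0556 and 0.215 in the test channel, where the shifts were −0.15 and −0.09 log2. Early meiotic genes were 7 lower of 16 (median −0.08), 2 under the block, with a shift of −0.08 ± 0.06 log2 that was below 0 at 4 of 5 times (exact permutation adjusted p = 0.0202).

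The methionine list stood higher with SCH9(2D3E) and passed in 22 of 27 settings, and purine synthesis passed in fewer. Of the 26 methionine genes 23 were higher and 0 lower (median 0.68 log2), and the list shift of 0.68 ± 0.31 (SD over 5 times) had an exact permutation p of 0.0123 and an adjusted p of 0.0256. Its median difference was 1.06 log2 against the empty plasmid, where the reference enters as given below, and 0.37 against SCH9(WT). MET5, of the sulfite reductase, was higher by 1.07 ± 0.17 log2, and MET8 and MET1, of siroheme synthesis, by 1.10 ± 0.13 and 1.06 ± 0.14 (SE). Purine synthesis had 11 of 20 genes higher and 1 lower (12 and 1 over the list alone; median 0.40), with ADE4, the first enzyme of the pathway, higher by 0.80 ± 0.06, and a list shift of 0.27 ± 0.12 (exact permutation p = 0.0206, adjusted p = 0.0397). It passed in 15 of 27 settings, and not with the scanner software's log ratios or the series matrix (shift 0.29, permutation adjusted p = 0.0815), and its median difference was 0.14 log2 in Cy5. Of 33 G1/S genes 18 were higher and 4 lower (median 0.12; shift 0.11 ± 0.04), among them the ribonucleotide reductase gene RNR1 (0.73 ± 0.12 log2) and the cyclin gene CLN1 (0.61 ± 0.12), and with the block 11 were higher and 1 lower. Histone genes (4 of 8 higher, median 0.11; shift 0.17 ± 0.09; 1 under the block), alpha-cell genes (2 of 4, or 3 over the list alone, median 0.15; shift 0.21 ± 0.08; 1 under the block) and the plasmid-borne SCH9 and URA3 (2 of 2, median 0.30; shift 0.30 ± 0.09; 1 under the block) passed too. For G1/S, histone, alpha-cell and plasmid-borne genes the exact permutation adjusted p was 0.0139. In the test channel the histone shift was −0.02 log2 and the alpha-cell shift 0.02 (permutation adjusted p = 0.865 and 0.88), and the difference of URA3 was −0.19 log2, against 0.44 ± 0.06 in the ratio.

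The remaining lists did not pass the exact permutation test with the loess ratios. The Gcn4 list had 23 of 46 genes higher and 1 lower (23 and 2 over the list alone; median 0.17 log2; shift 0.12, exact permutation adjusted p = 0.209), and 10 higher with the block. It passed in the test channel (0.28 log2, permutation adjusted p = 0.0278), as did the retrograde response (0.32, permutation adjusted p = 0.0222), which also passed with median centring (0.27, permutation adjusted p = 0.0317). Nitrogen catabolite repression had 4 higher and 8 lower of 38 (3 and 6 over the list alone; median −0.05; shift −0.09, exact permutation adjusted p = 0.585). Its days opposed each other, with 23 lower and 2 higher on day 1 and 16 higher and 5 lower on day 2. The shift was 0.14 for the retrograde response (2 higher and 2 lower of 10; median 0.12; exact permutation adjusted p = 0.132) and −0.07 for glycolysis (3 and 1 of 17, 3 and 0 over the list alone; median 0.09; permutation adjusted p = 0.617). Respiratory genes (3 higher and 5 lower of 38, 2 and 3 over the list alone; median −0.01) had a shift of 0 (exact permutation adjusted p = 0.983), and so had the phosphate regulon (3 and 4 of 18; median 0.05; adjusted p = 0.992). The iron regulon (2 and 2 of 21, 1 and 1 over the list alone) had a median of 0.01 that median centring turned to −0.07, and G2/M genes (2 and 1 of 19) a median of 0.02 that it turned to −0.03 (permutation adjusted p = 0.636 for each). Daughter-specific genes (1 and 2 of 17, 1 and 1 over the list alone; median −0.05; adjusted p = 0.982), a-cell genes (0 and 1 of 7; median −0.04; adjusted p = 0.333, and 0.0317 with median centring at −0.23) and mitochondrially encoded genes (0 and 0 of 7; median −0.02; adjusted p = 0.744) complete the permutation results, of which 14 of 27 passed.

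**Figure D2:**
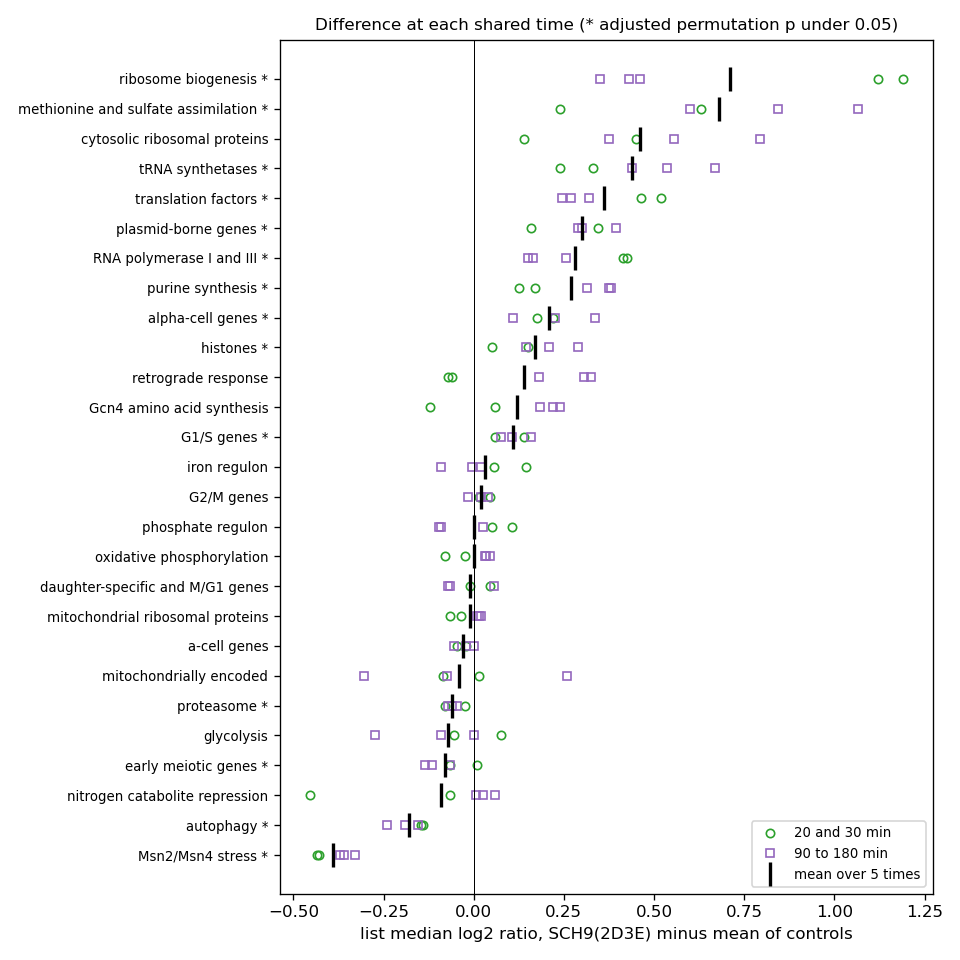
Difference of each list median (log2 ratio, SCH9(2D3E) minus the mean of both controls) at the 5 shared times, circles for 20 and 30 min and squares for 90 to 180 min, with the mean as a bar. A star marks an exact permutation adjusted p under 0.05, as for ribosome biogenesis (0.71 log2) and the Msn2/Msn4 list (−0.39 log2); median centring turned the medians of the iron regulon and G2/M genes below 0.

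Camera with the preset correlation called 13 of the lists for SCH9(2D3E) minus controls. The smallest adjusted p was 4.80e-25 for ribosome biogenesis, followed by 1.54e-17 for cytosolic ribosomal proteins, and with an estimated correlation the adjusted p was 0.432 for both and 0.333 to 0.565 over the 13 lists. Across all comparisons only the phosphate regulon, for SCH9(WT) minus empty plasmid, kept its call with an estimated correlation.

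SCH9(2D3E) was also set against SCH9(WT) alone, the comparison in which both plasmids carry SCH9 (n = 5 and 6). The Cy3 references of the 2 plasmids differed too, by a median of −0.28 log2 in ribosome biogenesis and −0.19 in cytosolic ribosomal proteins. It gave 2877 genes in limma, 1509 higher and 1368 lower, with 59 higher and 8 lower by at least 2-fold. With the scanner software's log ratios 1390 were higher and 1747 lower. Ribosome biogenesis had 129 of 138 genes higher and 0 lower (132 over the list alone; median 0.76 log2), and cytosolic ribosomal proteins 130 of 137 higher and 0 lower (133 over the list alone; median 0.71). Msn2/Msn4 genes were 37 lower and 0 higher of 50 (39 lower over the list alone; median −0.46). Methionine genes were 14 higher and 0 lower of 26 (15 higher over the list alone; median 0.37), and purine genes 10 higher and 3 lower of 20 (10 and 4 over the list alone; median 0.28). At the 5 shared times the shifts of these 5 lists were 0.77 ± 0.22, 0.70 ± 0.36, −0.47 ± 0.13, 0.41 ± 0.21 and 0.12 ± 0.08 log2 (SD). The smallest exact permutation p that 32 arrangements allow is 0.0625, so no list could pass by that test. Within day 1 the count was 2108 and within day 2 it was 3461, and the block by plasmid and day left 1176 (749 higher, 427 lower). With 1 value per plasmid and day limma called 0 genes, with 1302 at an unadjusted p under 0.05.

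Against the empty plasmid, which asks what SCH9(2D3E) changed relative to chromosomal SCH9 only, limma called 2097 genes (n = 5 and 6), 1196 higher and 901 lower, with 26 higher and 0 lower by at least 2-fold. With the scanner software's log ratios 1057 were higher and 1205 lower, and with median centring 1024 and 895. Methionine genes led, 25 of 26 higher (all 26 over the list alone; median 1.06 log2), followed by ribosome biogenesis with 112 of 138 higher (126 over the list alone; median 0.60; within day 1 all 138 were higher, and within day 2 89 were higher and 4 lower, with a median of 0.24) and 17 of 20 purine genes (median 0.48). The reference enters the methionine difference. In Cy3 that list rose from day 1 to day 2 by 1.54 log2 with the empty plasmid and by 0.99 with SCH9(2D3E). Of the cytosolic ribosomal protein genes 19 of 137 were higher (0 over the list alone; median 0.25, with 0.52 in Cy5 and 0.28 in Cy3). The block by plasmid and day left 592 genes, 439 higher and 153 lower. With 1 value per plasmid and day limma called 0, with 894 at an unadjusted p under 0.05.

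An extra copy of wild-type SCH9 was assessed as SCH9(WT) minus empty plasmid (n = 6 each). Limma called 259 genes, 120 higher and 139 lower, of which 1 was higher by at least 2-fold. MET3 was higher by 1.12 ± 0.24 log2 (SE), MET14 by 0.98 ± 0.16 and the cystathionine beta-lyase gene STR3 by 0.90 ± 0.13, and the difference was −0.96 ± 0.07 for PHO5, the secreted acid phosphatase, and −0.95 ± 0.20 for PHO84, a phosphate transporter (limma adjusted p at most 0.0362). Of the methionine genes 15 of 26 were higher (22 over the list alone; median 0.62), and of the cytosolic ribosomal protein genes 52 of 137 were lower (121 over the list alone; median −0.44). The phosphate regulon had 4 lower and 1 higher of 18 genes (10 and 1 over the list alone; median −0.19), with a camera adjusted p of 7.11e-08, and 0.00472 with an estimated correlation. The exact permutation test passed 0 of 27 lists (smallest p 0.0312, adjusted p = 0.169).

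These differences between SCH9(WT) and the empty plasmid lay mostly in the reference channel. In Cy3 the ribosomal protein median differed by 0.46 log2 and in Cy5 by 0, and the methionine median by −0.48 in Cy3 and 0.17 in Cy5. PHO84 and PHO5 were higher in Cy5 with SCH9(WT), by 1.75 and 0.38 log2, opposite to their ratios. The count was 513 within day 1 and 2128 within day 2, but of 286 genes called on both days 57 had the same sign where independent lists would share 91. Ribosome biogenesis was higher on day 1 (55 genes, median 0.28 log2) and lower on day 2 (133 genes, median −0.39). With slide as a random block limma called 13 genes and with plasmid and day as a block 0, with 117 at an unadjusted p under 0.05 for 1 value per plasmid and day.

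Late arrays (120 and 180 min) were set against early arrays (20 and 30 min) to ask how the response changed with time over all plasmids. This difference cannot be told apart from the day on which the arrays were read, or from whatever else differed between the 2 sets of arrays. Limma called 4748 genes, 2428 higher and 2320 lower, 444 and 262 of them by at least 2-fold. With the scanner software's log ratios 2247 were higher and 2569 lower, and with median centring 2296 and 2177. HSP30 was higher late by 4.57 ± 0.24 log2 (SE), GRE1 by 4.53 ± 0.14 and SSA3, a heat-inducible chaperone, by 4.27 ± 0.22, while the difference was −4.16 ± 0.13 for ADH4, −4.10 ± 0.08 for FCY21, of a permease family for purines and cytosine, and −3.50 ± 0.04 for LYS9, of lysine synthesis. For LYS9 the difference lay in the reference, with Cy3 levels of 9.52 to 9.99 on day 1 and 12.60 to 13.34 on day 2, and Cy5 levels of 9.65 to 10.12 and 9.21 to 10.30. Ribosome biogenesis was higher late in 137 of 138 genes (median 1.67 log2), purine synthesis in 17 of 20 with 2 lower (1.16) and the respiratory chain in 30 of 38 with 3 lower (0.37). Cytosolic ribosomal proteins were lower in 107 of 137 with 9 higher (−0.80), mitochondrial ribosomal proteins in 63 of 69 with 1 higher (−0.48) and glycolysis in 16 of 17 (−0.67, with −0.19 in Cy5 and 0.60 in Cy3). Limma's camera called these 6 (adjusted p = 9.67e-20, 6.54e-05, 3.87e-05, 1.20e-09, 7.09e-12 and 6.54e-05). With an estimated correlation the adjusted p was 0.788 for cytosolic ribosomal proteins and 0.651 for the others.

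Within day 2 alone, 120 and 180 min against 60 and 90 min gave 2508 genes in limma, 1499 higher and 1009 lower. Ribosome biogenesis was higher at the later times in 132 of 138 genes (0.37 ± 0.20 log2, SD over genes), cytosolic ribosomal proteins in 121 of 137 (0.55 ± 0.26) and the respiratory chain in 37 of 38 with 1 lower (0.31 ± 0.14). Cytosolic ribosomal protein genes were therefore higher late within day 2 and lower late than early over both days.

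The last comparison asked whether the time course itself ran at another slope on log2 time with SCH9(2D3E). Limma called 1469 genes, 625 with a higher and 844 with a lower slope than the controls, and 1 was lower by at least 1 log2 per doubling of time. Ribosome biogenesis had a lower slope in 89 of 138 genes and a higher one in 1 (99 and 2 over the list alone; median −0.25 log2 per doubling), and cytosolic ribosomal proteins a higher slope in 58 of 137 and a lower one in 2 (64 and 2 over the list alone; 0.13). Nitrogen catabolite repression had a higher slope in 25 of 38 genes (median 0.16; camera adjusted p = 3.12e-12, and 0.0651 with an estimated correlation). BTN2, a chaperone-like factor of protein sorting, had the lowest slope difference (−1.01 ± 0.13, SE) and RPL3, of the large subunit, and the urea permease gene DUR3 the highest (0.63 ± 0.04 and 0.63 ± 0.08; limma adjusted p at most 0.000717). The block by plasmid and day left 47 genes (42 higher, 5 lower), and the day 2 arrays alone gave 202 (150 higher, 52 lower). The balance of slopes also turned with the scanner software's log ratios (594 higher, 572 lower), but not with median centring (1163 higher, 1630 lower). Within day 2 the median slope difference was 0.05 for ribosome biogenesis, opposite in sign, and 0.43 for cytosolic ribosomal proteins. Slopes span both days, so a difference between the 2 sets of arrays enters them.

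**Figure D3:**
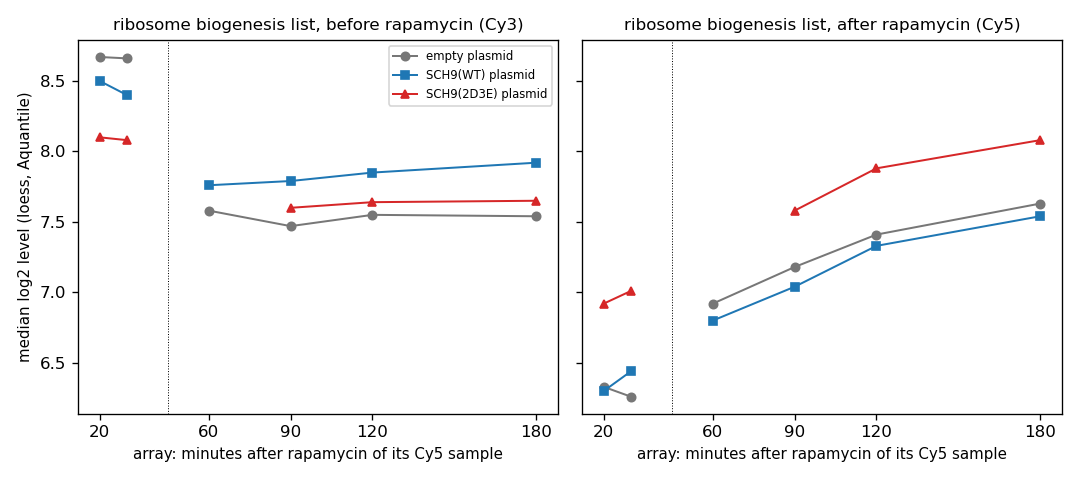
Median log2 level of the ribosome biogenesis list (after loess and Aquantile) in each channel of each array, against the minutes after rapamycin of the array's Cy5 sample, for the 3 plasmids. The Cy3 samples were all taken before the drug, and the dotted line separates day 1 from day 2.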

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

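The tests of reference RNA, of day and of a uniformly weaker response were chosen after the results were seen, while the rearrangements of labels were planned. Each result listed here is a difference between plasmids or times that passed its own test. For SCH9(2D3E) minus controls, the lists that passed the exact permutation were ribosome biogenesis (mean shift 0.71 log2), RNA polymerase I and III (0.28), translation factors (0.36), tRNA synthetases (0.44), methionine and sulfate assimilation (0.68), purine synthesis (0.27), histones (0.17), G1/S genes (0.11), alpha-cell genes (0.21) and plasmid-borne genes (0.30). Those with a lower ratio were the Msn2/Msn4 list (−0.39), autophagy (−0.18), the proteasome (−0.06) and early meiotic genes (−0.08). Limma called 2939 genes for SCH9(2D3E) minus controls, 2877 against SCH9(WT), 2097 against the empty plasmid, 259 for SCH9(WT) minus empty plasmid, 4748 for late minus early and 1469 for the slope difference.

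Labels were rearranged within times, or within plasmids for late minus early. For SCH9(2D3E) minus controls only the real arrangement, 1 of 100, gave 2939 genes, and the highest other gave 1344. For late minus early 1 of 100 arrangements gave 4748 and the highest other 3409. For SCH9(2D3E) minus controls, chance can be excluded only where single arrays are exchanged, and not between cultures. The real labels of late minus early coincide with the day and the rearrangements mix the days, so that test cannot separate time from day. For the slope difference 3 of 100 arrangements gave 1469 or more, the highest 2467, which lies under the share of 0.05 set beforehand, but a wrong arrangement called more genes than the real one. Arrays of the same plasmid and day had nearly the same Cy3 profile (median r 0.999 across genes, which are not independent), most arrangements part them, and those that keep them together are too few for a share under 0.05. For SCH9(2D3E) minus controls the count was 1406 with plasmid and day as a block and, with 1 value for each, 0 in limma (1427 at an unadjusted p under 0.05, lowest adjusted p 0.178). The 16 splits are too few for a share under 0.05 against SCH9(WT) (real 2877, highest other 0) and against the empty plasmid (real 2097, highest other 0), where 1 of 16 was as large. For SCH9(WT) minus empty plasmid 2 of 32 splits gave 259 or more, so chance cannot be excluded. The other one gave 697 and swapped the labels at all times of day 2, and the values within days were 513 and 2128.

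Ribosome biogenesis genes were less reduced with SCH9(2D3E) than in the controls, by a median of 0.67 log2. A different reference RNA as the whole cause is argued against by the test channel, where 137 of 138 genes were higher and the median difference was 0.46 log2 (SD over genes 0.24). That channel was scaled together with the reference channel, so it is not wholly free of the reference. A response that was weaker by 1 share for all genes and all times is argued against by mitochondrial ribosomal proteins. Averaged over all times, and so over both days, ribosome biogenesis lost 78.4 percent of the control response, which predicted a difference of 0.43 log2 there. The value observed was −0.01 (SD over genes 0.08). A share that changed with time was not tested, and the 2 lists ran on unlike courses in the controls. Ribosome biogenesis went from −2.08 log2 at 20 min to −0.05 at 180 min, and mitochondrial ribosomal proteins from 0.01 to −0.7. An effect of the Sch9 allele on ribosome assembly genes may remain as a hypothesis, and so does any other difference between the cultures of the plasmids, which the design cannot separate from the plasmid.

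SCH9(WT) minus empty plasmid is the pattern for which a difference between the plasmids' reference RNAs may account. Over the 259 genes called, the median difference in the direction of the ratio was 0.28 log2 in the ratio, 0.06 in Cy5 and −0.20 in Cy3. In Cy5 208 of the 259 differed in the ratio's direction (SD over genes 0.2), so the reference may not account for all of it. The genes were called by the ratio, which holds Cy5, so that count is not a separate test. An effect of the extra SCH9 copy was not tested apart from the cultures and stays open.

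Ribosome biogenesis genes were higher at 120 and 180 min than at 20 and 30 min by a median of 1.67 log2. A changed reference RNA on the second day as the whole cause is argued against by the Cy5 level, which was higher late by 0.96 log2 (131 of 138 genes, SD 0.54). The Cy5 level was scaled together with Cy3 and is not wholly free of it. A step between days with no change over time is argued against by the rise within day 2 from 60 and 90 to 120 and 180 min, 0.37 log2 (SD 0.20). A recovery of ribosome assembly transcripts under rapamycin may be a candidate explanation for that part, while how much of the 1.67 comes from the change of day cannot be told apart from time.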

How the results depend on the processing

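The values within days, with plasmid and day as a block, with 1 value per plasmid and day, within day 2 only and, for late minus early and the slope, in the test channel were chosen after the data were seen. The cause of a shift below was not tested unless stated. With every scaling run the median of all genes lay, at 2 decimals, between −0.04 and 0.04 log2. Each of these scalings centres the arrays, so that range follows from the processing and is no test of it.

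Without a time term the time course itself enters the error, and limma called 2562 genes for the SCH9(2D3E) response, 486 for SCH9(2D3E) minus SCH9(WT), 506 minus controls, 151 minus empty plasmid, 2 for SCH9(WT) minus empty plasmid and 25 for the slope difference. With slide as a random block, the counts were 1209 for SCH9(2D3E) minus empty plasmid and 13 for SCH9(WT) minus empty plasmid. With plasmid and day as a random block, they were 1176 against SCH9(WT), 1406 against controls, 592 against the empty plasmid, 0 for SCH9(WT) minus empty plasmid and 47 for the slope. ZPR1 then had a slope difference of 0.07. No other count moved by over 1.5 times under either block. With 1 value per plasmid and day (6 values), the SCH9(2D3E) response had 2499 genes and each plasmid difference 0, with 1427 genes for SCH9(2D3E) minus controls, 1302 against SCH9(WT), 894 against the empty plasmid and 117 for SCH9(WT) minus empty plasmid at an unadjusted p under 0.05. MF(ALPHA)2 then stood at 0.02 log2 in the controls.

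In the test channel, where the reference RNA enters only through the scaling, the counts were 1251 against SCH9(WT), 1603 against controls, 1345 against the empty plasmid, 5 for SCH9(WT) minus empty plasmid and 617 for the slope. The autophagy (−0.15 log2), proteasome (−0.09) and alpha-cell (0.02) lists of SCH9(2D3E) minus controls no longer passed there, while the cytosolic ribosomal protein (0.59), retrograde response (0.32) and Gcn4 (0.28) lists did. The sign turned there for the histone list (−0.02 log2) and URA3 (−0.19) in SCH9(2D3E) minus controls, and for PHO5 (0.38), PHO84 (1.75) and SPL2 (0.74) in SCH9(WT) minus empty plasmid.

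Median centring gave 58 genes for SCH9(WT) minus empty plasmid, 69 percent of them higher against 46.3 percent with loess, and 2793 for the slope. In the control response it turned ACO1 (0.15 log2), HHF1 (0.06), STE2 (−0.38), MFA2 (−0.50), COB (0.05) and VAR1 (−0.05). With the scanner software's log ratios, or the series matrix, 46.7 percent of the genes called for SCH9(2D3E) minus empty plasmid were higher, against 57 percent with loess, as were 44.9 against 53.9 percent minus controls and 44.3 against 52.5 percent minus SCH9(WT). SCH9(WT) minus empty plasmid had 47 genes at the 5 shared times, 76 with only its plasmids in the fit and 2250 with array weights, which gave 237 for the slope.

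Within day 1, SCH9(WT) minus empty plasmid had 513 genes, and within day 2 it had 2128. Within day 1 the control response turned for LYS9 (0.17 log2), ACO1 (0.07), IDH1 (−0.25), COX7 (−0.03), COX5A (−0.29), PHM7 (−0.32), CLB1 (0.17), MF(ALPHA)2 (0.54), MFA2 (−0.07), BAR1 (0.08), HOP1 (0.62) and COX1 (0.15), and SCH9(2D3E) minus controls for RPL3 (−0.13), CIT2 (−0.06) and RPN4 (0). Within day 2 the control response turned for PYC1 (−0.07), ADH5 (−0.34) and SAG1 (−0.37). With day 2 only, late minus early had 2508 genes and the slope difference 202, and the slopes of GDH1 (−0.22), ZPR1 (0.03) and RPF1 (0.06) turned.

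Each array was left out in turn. The counts ran from 32 to 615 for SCH9(WT) minus empty plasmid, from 614 to 1690 for the slope, and from 0 to 15 lists for the permutation of SCH9(2D3E) minus controls. For SCH9(WT) minus empty plasmid every array from 30 to 180 min of both plasmids moved the count by over 1.5 times. It was 615, 47, 32, 38 and 45 without the empty plasmid arrays of 30, 60, 90, 120 and 180 min, 400, 47, 34, 33 and 64 without those of SCH9(WT), and 114 and 76 without SCH9(2D3E) at 90 and 120 min. The slope count was 614, 896 and 904 without SCH9(2D3E) at 20, 120 and 180 min. Without SCH9(2D3E) at 20, 30, 90, 120 and 180 min, 0, 9, 8, 7 and 9 lists passed. Leaving out such an array also leaves fewer arrangements, which raises the smallest possible p. Without the 20 min array the shift was still 0.61 log2 for ribosome biogenesis, 0.49 for tRNA synthetases and 0.79 for the methionine list (permutation adjusted p = 0.0606 for each). Leaving out 1 array gave 2353 to 2982 genes for SCH9(2D3E) minus controls.

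An estimated correlation in camera left 0 of 13 lists called for SCH9(2D3E) minus controls. Late minus early has no fit without a time term. The fit with only the plasmids compared equals the full fit for SCH9(2D3E) minus controls. The headers hold no scan date, and day as a fixed block is aliased with time. Of 285 values of named genes, 283 kept sign and call without background correction, 270 with median centring, 266 with slide as a block and 231 with plasmid and day as a block, where 53 lost the call. Without a time term 155 of 275 did and 120 lost the call, and with 1 value per plasmid and day 118 of 265 did and 146 lost it.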

Other observations

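The Cy3 levels, of RNA sampled before rapamycin, differed between the later and the earlier arrays, and what separated the 2 sets was not recorded. In the Cy3 channel, day 2 minus day 1, cytosolic ribosomal protein genes stood lower by a median of −1.80 log2 with the empty plasmid, −1.05 with SCH9(WT) and −0.93 with SCH9(2D3E), and ribosome biogenesis genes by −1.18, −0.62 and −0.40. Msn2/Msn4 genes stood higher by 1.62, 0.98 and 1.09 log2, and methionine genes by 1.54, 0.87 and 0.99. Genes under nitrogen catabolite repression stood lower by −0.97, −1.21 and −1.48. Between the days 881 genes differed at least 2-fold with the empty plasmid, 527 with SCH9(WT) and 498 with SCH9(2D3E), against 3 for SCH9(WT) minus empty plasmid over both days. No test was made of these levels, since no replicate culture is recorded.

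Within day 2 the methionine and sulfate assimilation list went the other way from the ribosome lists, with 14 of 26 genes lower and 0 higher at 120 and 180 min than at 60 and 90 min (median −0.29 log2, limma). G1/S genes did the same, with 23 of 33 lower and 0 higher (median −0.16).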
